A study of Gallus gallus with 6 samples.

How the data were processed

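Open chromatin was profiled by ATAC-seq in abdominal fat of 6 chickens, 3 of the line labelled FL and 3 of the line labelled LL. Each library came from a different bird, per the series' design text. Nuclei were released from a cell suspension, cut with Tn5 transposase, amplified and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, BWA, SAMtools, bedtools 2.30.0 and MACS3 3.0.0b1, and the chicken assembly GRCg7b. The settings of these tools, the removal of duplicates or of reads with several matching places, and any shift of read ends for the Tn5 cut are not given in the sources used here.

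The deposited files are 1 peak list per library, and no pooled list was used. For each peak the authors' list gives chromosome, start, end, a score, a fold enrichment over local background, −log10 p, −log10 q and the summit position. The score in the deposited lists is 10 times −log10 q, rounded down, in all but at most 0.0518% of the peaks of any list. The lowest −log10 q in the deposited lists lay between 2.01 and 2.03, so the lists end near a q-value of 0.01. The fold enrichment is a ratio that the authors' peak caller computed within 1 library. It was used here only to describe and rank peaks within that list. The lists hold peaks on 41 chromosomes and none on unplaced sequences or the mitochondrion.

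The lists give no read totals. In MACS output the fold enrichment equals (pileup + 1) / (background + 1), and −log10 p is the upper tail of a Poisson distribution with that background. The whole-number pileup and the background of each peak were solved from these 2 columns within a relative tolerance of 1e-04. A solution was found for 100% of the peaks of all 6 lists. The lowest background of a list is the genome-wide background, which is proportional to the number of fragments times the length they are extended to. It stands here for depth. It cannot separate reads from fragment length, so it was also divided by the shortest peak of the list, a choice made after the data were examined. On 19902 simulated peaks the solver recovered the pileup of 100%.

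Peaks of all 6 libraries were merged into union regions where they overlapped by at least 1 bp. A region was occupied in a library if a peak of that library lay in it. Genes came from a RefSeq table of GRCg7b with 25356 genes on chromosomes, 17839 of them protein-coding. This table has no strand and no exons, and no genome sequence was used. The promoter of the planned tests was therefore replaced by the gene end, within 1 kb of either annotated end of a gene. Exons and introns were not separated. The planned motif search and GC content of peaks were not run. Summits were classed as at a gene end, inside a gene or outside genes, in that order.

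Co-occupancy of 2 libraries was the log2 odds ratio over regions occupied in at least 1 of the other 4. Regions called in one line were those occupied in 3 of 3 libraries of that line and 0 of 3 of the other. Their expected number came from a conditional model of the regions called in exactly 3 libraries, with 1 effect per library and 20 possible patterns. In 20 simulated data sets of 100148 regions with library effects and nothing planted, observed over expected for FL-only regions averaged 1.01 ± 0.0616 (SD). With 200 planted FL-only regions it averaged 1.70 ± 0.0553. The simulations assume that libraries act independently of each other within a region. The data depart from this: patterns that mix the lines had ratios from 0.0948 to 32.3. The simulated SD therefore does not measure the spread of the ratio in these data.

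Gene lists, 16 in number and with 258 genes, were fixed before the data were examined, and 235 of these genes were found as coding genes in the table. The erythroid list had 9 of 15 genes in the table, below the required 80%, and its test is void, leaving 15 lists. The share of a list's genes with an occupied end was compared with all other coding genes by Fisher's exact test in each library, with Benjamini-Hochberg adjustment over 90 tests. Distal density was the number of occupied regions away from any gene end, per 100 kb of windows of 50 kb around both ends of a gene. It was divided by the mean of all coding genes and ranked among 10000 random lists matched on local gene number. On simulated lists of 15 genes, 5.5% of unchanged lists and 98.5% of lists with density raised 2 times fell under 0.05 in this test. Random lists of 15 genes fell under 0.05 in 6.2% of Fisher tests of gene ends. FL and LL were compared by an exact two-sided permutation of the 20 assignments of libraries to lines. With 3 libraries per line the smallest p this allows is 0.1, so no such comparison could pass 0.05.

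The text names genes by a rule fixed before the data were examined. It takes the 10 regions per line with the best poorest rank, by the nearest coding gene with a symbol within 100 kb. From each list it takes up to 4 genes whose occupied libraries differ by at least 2 between lines, and up to 3 genes occupied in all 6 libraries with the best poorest rank. PPARG, CEBPA, FABP4, ADIPOQ, LPL and PLIN1 are always named. A gene that this rule takes is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

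Alternatives were peaks with −log10 q of at least 5, equal list lengths, windows of 250 bp either side of summits, 50% reciprocal overlap, the Jaccard index, gene ends within 3 kb, distal windows of 20 kb, regions in at least 2 of 3 libraries, each library left out, and pairing by replicate number. Added after the data were examined were lists without chromosomes Z, W, 16 and 31, random lists matched on gene length, and only peaks of at least 178 bp. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.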

Results

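Chromatin accessibility was measured by ATAC-seq, in which the transposase Tn5 cuts DNA that is not covered by nucleosomes, in abdominal fat of 6 chickens. The labels name the lines only as FL and LL of the NEAUHLF population, which is known as a population of broilers selected in opposite directions for abdominal fat, with a fat and a lean line. Each line had 3 birds and 1 library per bird. The peak lists held 58060, 32066 and 23188 peaks in FL replicates 1 to 3 and 73410, 23316 and 15628 in LL replicates 1 to 3. The genome-wide background, which stands for depth, was 8.26, 4.90 and 2.23 fragments over a base in FL and 8.1, 5.80 and 8.73 in LL. LL replicate 3 thus had the highest background and the shortest list. Divided by the shortest peak of the list, the background was highest in FL replicate 1, at 0.0565, against 0.0490 in LL replicate 3. Positions are in GRCg7b.

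The first question was which genes had open ends in abdominal fat and whether the lines differed. PPARG, the nuclear receptor that drives fat cell formation (chromosome 12, 5019526 to 5074079), had a peak within 1 kb of an annotated end in all 6 libraries, as did FABP4, a fatty acid carrier of fat cells, CEBPD, a transcription factor of early adipogenesis, and LPL, which releases fatty acids from circulating lipoproteins. For LPL it was not the same end in every library. CEBPA and PLIN1, which coats lipid droplets, were occupied in all FL libraries and in LL replicates 1 and 2. ADIPOQ, the gene of the hormone adiponectin, was occupied in FL replicates 1 and 2 and in all LL libraries. The strongest PPARG peak ranked within the top 25.8% of the list by q-value in every library and within the top 3.93% in FL replicate 2, whereas the LPL peak ranked no better than 43.6% in any library. The adipocyte identity list had 78.9% ± 13.9 of its 19 genes occupied in FL and 77.2% ± 21.9 in LL (SD, n = 3 each), a difference of 1.75 points (exact permutation p = 1).

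In the full lists, most genes of lipid and glucose metabolism had an occupied end in the average library of either line, with a wide spread between libraries. All coding genes were at 69.5%, 56.6% and 54.7% in FL replicates 1 to 3 and at 72.3%, 48.6% and 41.5% in LL replicates 1 to 3. None of the metabolic lists, nor the regulators of adipogenesis, passed Fisher's exact test in any library. At equal list lengths the insulin and glucose list was at 61.1% to 77.8% and the lipolysis list at 50% to 62.5%. The list of fatty acid and triglyceride synthesis was then at 50% to 70% in FL but at 40% to 50% in LL. Regulators of adipogenesis were at 42.3% to 57.7% in FL and 38.5% to 50% in LL. The values that follow are of the full lists. In the list of fatty acid and triglyceride synthesis, 76.7% ± 7.64 of 20 genes were occupied in FL and 66.7% ± 23.6 in LL (SD, n = 3 each; exact permutation p = 0.9). Its best-ranked genes present in all 6 libraries were MOGAT1, an acyltransferase of triglyceride synthesis that stayed within the top 5.93% of every list, FASN, the fatty acid synthase, and ME1, which supplies NADPH for lipid synthesis. The list of lipolysis and fatty acid oxidation had 70.8% ± 9.55 of 16 genes occupied in FL and 66.7% ± 13.0 in LL, with ETFDH, PLIN2 and CPT1A leading. The insulin and glucose list had 79.6% ± 8.49 of 18 genes in FL and 75.9% ± 17.0 in LL, led by PIK3CA, PIK3R1 and PRKAA1, which encode parts of the insulin and energy-sensing kinases. Regulators of adipogenesis had 70.5% ± 15.5 of 26 genes in FL and 61.5% ± 27.7 in LL, led by KLF3, RB1 and KLF7. ZNF423, a zinc finger factor of preadipocytes, stayed within the top 12.6% of every list.

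Lists of other cell types differed between libraries of the same line. In the full lists, endothelial genes were occupied at 80% in FL replicate 1 and 93.3% in LL replicate 1, against 20% to 26.7% in the other 4 libraries. Fibroblast and progenitor genes were at 80% and 95% in the same libraries, against 15% to 45%, and myeloid genes at 85.7% and 92.9%, against 21.4% to 50%. At equal list lengths the pair was at 33.3% and 40% for endothelial genes, against 6.67% to 20% in the other libraries, at 20% and 15% for fibroblast genes, against 15% to 30%, and at 21.4% and 28.6% for myeloid genes, against 21.4% to 42.9%. All coding genes were also highest in these libraries, at 69.5% and 72.3%, against 41.5% to 56.6% in the other 4. DPP4, MFAP5 and TWIST1 of the fibroblast list, IRF8 and LYZ of the myeloid list and RHOH of the lymphocyte list were occupied in all 6 libraries, as were WT1 and MSLN of the mesothelial list, APOA1 of the hepatocyte list and TNNT3 of the skeletal muscle list. Neuronal genes were at 25% and 8.33% in FL replicates 1 and 3, at 25% in LL replicate 1, at 0% in LL replicates 2 and 3, and at 41.7% in FL replicate 2, which fell to 0% there with −log10 q of at least 5 and at equal list lengths. Lymphocyte genes averaged 40.5% in FL and 31% in LL, smooth muscle and pericyte genes 33.3% and 22.2%, mesothelial genes 50% and 37.5%, skeletal muscle genes 23.3% and 16.7% (10% and 16.7% with −log10 q of at least 5, and 10% in every library at equal list lengths), and hepatocyte genes 19.4% and 25%. The 9 erythroid genes found, too few for a test, averaged 37% and 44.4%. The housekeeping list averaged 92.3% in FL and 87.2% in LL, led by RPL4, SDHA and EEF1A1.

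**Figure D1:**
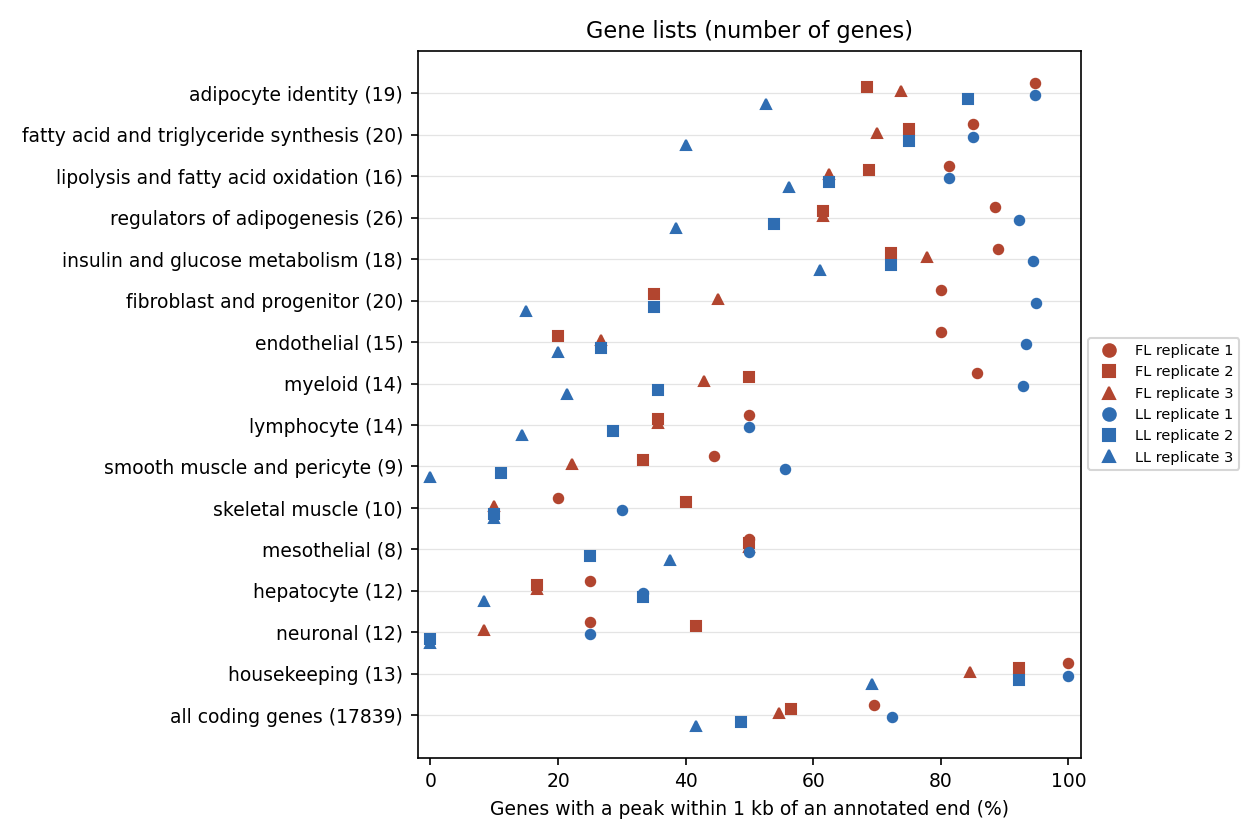
Share of the genes of each list with a peak within 1 kb of an annotated end (horizontal axis, %), 1 point per library, red for FL and blue for LL, with the replicate as the point's shape. Endothelial, fibroblast and myeloid genes were highest in FL replicate 1 and LL replicate 1 in these full lists, at equal list lengths only the endothelial genes were (33.3% and 40%), and the lines overlap in all 15 lists.

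Against all other coding genes, 2 of 90 Fisher's exact tests of lists in libraries were higher after Benjamini-Hochberg adjustment and 12 were lower. Both higher tests were in LL replicate 2, with 16 of 19 adipocyte identity genes (84.2% against 48.6%, Fisher's exact test, adjusted p = 0.0206) and 12 of 13 housekeeping genes (92.3% against 48.6%, adjusted p = 0.0206). The lower tests were neuronal genes in 5 libraries, skeletal muscle genes in 3, hepatocyte genes in 3 and endothelial genes in FL replicate 2. Between the lines the lowest exact permutation p of the 15 lists was 0.3, for the neuronal list (means 25% in FL and 8.33% in LL, but 11.1% and 8.33% with −log10 q of at least 5), and the adjusted value was 0.964 (smallest possible p 0.1). With −log10 q of at least 5, 0 of the tests were higher.

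Distal regions were denser around the genes of the adipocyte identity list than around other genes. Around the 19 adipocyte identity genes the density was 1.84 ± 0.12 times that of all coding genes in FL and 2.02 ± 0.156 times in LL (SD, n = 3 each), the highest mean of the 15 lists in both lines. It exceeded the random lists in 5 of 6 libraries, all but FL replicate 2 (adjusted permutation p between 0.0036 and 0.0144, and 0.121 in FL replicate 2). Endothelial genes followed at 1.53 ± 0.261 in FL and 1.69 ± 0.163 in LL and passed in FL replicate 1 and LL replicates 1 and 2. Regulators of adipogenesis and the fibroblast list passed in FL replicate 1 and LL replicate 1, and the insulin and glucose list in LL replicate 1. The lists of fatty acid and triglyceride synthesis (1.1 in FL and 1.33 in LL) and of lipolysis and fatty acid oxidation (1.25 and 1.42) passed in 0 of 6 libraries. In all, 13 of 90 tests were higher and 0 were lower. At an equal list length of 15628 peaks 6 were higher, and the number was 7 without LL replicate 1 and 8 without FL replicate 1.

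The mean ratio of distal density to that of all coding genes was higher in LL in 11 of the 15 lists and higher in FL in 4, in a design where no list could pass the test. The adipocyte identity ratio differed by -0.177 between FL and LL (exact permutation p = 0.3, adjusted 0.75). The lists of lipolysis and fatty acid oxidation (1.25 in FL and 1.42 in LL) and of hepatocyte genes (0.999 and 1.19) had the lowest exact permutation p, 0.2, and no list passed after adjustment (smallest possible p 0.1).

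A few list genes had an end occupied in at least 2 more libraries of one line. In FL these were 12 genes. KLF2, KLF5 and KLF9, Krüppel-like transcription factors, IGF1R, the receptor of insulin-like growth factor 1, FBN1, which builds extracellular microfibrils, SPI1 and CD74 of the myeloid list, ACTA2 of smooth muscle and ALDH1A2 of the mesothelial list were occupied in all 3 FL libraries and in LL replicate 1 alone. MYLK, SYT1 and NEFL were occupied in FL replicates 1 and 2 and in no LL library. In LL these were TIE1, an endothelial receptor, with all 3 LL libraries against FL replicate 1 alone, and F2, the prothrombin gene, with LL replicates 1 and 2. A difference of at least 2 libraries in the same direction was also found for 6 of the 12 FL genes and 0 of the 2 LL genes with −log10 q of at least 5, for 5 and 1 at equal list lengths, and for 5 and 2 with peaks of at least 178 bp. KLF2 and ALDH1A2 had it in all 3 of these settings, TIE1 in all but the first and MYLK in none. SYT1 and NEFL lost FL replicate 2 with −log10 q of at least 5. Over all 17839 coding genes, 1107 had at least 2 more FL libraries and 192 at least 2 more LL libraries. The 12 and 2 of 235 list genes are no larger shares than these. List genes thus did not differ between the lines more often than coding genes in general.

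The excess of FL genes was smaller when short peaks were left out. The shortest peak of a list was 146, 124 and 112 bp in FL and 166, 170 and 178 bp in LL, so every FL list reached shorter peaks than every LL list (exact permutation p = 0.1, the smallest possible). Library batches and the settings of the peak caller for each line are not given in the sources used here, so neither could be separated from line. With only peaks of at least 178 bp, 589 coding genes had at least 2 more FL libraries and 385 at least 2 more LL libraries, and of the list genes 6 and 7. That filter also changes the list lengths. At equal list lengths the numbers were 999 and 272 coding genes, and 15 and 7 list genes.

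Of all coding genes, 49 had an end occupied in all FL and no LL libraries, and 8 the reverse, against 32.5 and 1.65 expected from library effects. Observed over expected was thus 1.51 in FL and 4.86 in LL, the latter on 8 genes. For regions called in one line, given below, the order was the reverse, with 3.72 in FL and 1.35 in LL. Genes with ends within 1 kb of each other can share a peak, so the counts of genes are not independent. Among the LL genes LOC121106955 ends at 1782813 and LOC121106922 starts at 1782871 on chromosome 16. Among the FL genes SMC1B ends at 70481967 and RIBC1 starts at 70482115 on chromosome 1. The following were chosen after their values were seen. FL genes included ELOVL2, an elongase of long polyunsaturated fatty acids (chromosome 2, 62874967 to 62916414), TENM3 and CLSTN2, which encode cell surface proteins of neurons, and EDIL3, a secreted adhesion protein (chromosome Z, 62871709 to 63147874). The LL genes were DYSF, which repairs muscle membranes, HSPB7, a small heat shock protein, RNASET2, a ribonuclease, and 5 genes with LOC numbers, 4 of which lay on chromosome 16 between 1781636 and 1795548. Other ways of dividing the 6 libraries gave between 3 and 461 such genes, against 57 for FL and LL.

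The next question was which regions were open in one line alone. Of 100148 union regions, 209 were called in all FL and no LL libraries and 85 in all LL and no FL libraries. The FL-only regions were the narrower ones, with a median width of 311 bp against 564 bp for LL-only regions. All regions called in exactly 3 libraries had a median width of 556 bp. The median peak width of the whole lists was 350, 198 and 190 bp in FL and 431, 326 and 339 bp in LL replicates 1 to 3. Of the FL-only regions 56 lay at gene ends, 83 inside genes and 70 outside genes, and of the LL-only regions 11, 60 and 14. Gene ends thus held 26.8% of FL-only and 12.9% of LL-only regions, against 17.0% of all regions called in exactly 3 libraries. Of the FL-only regions 16, and of the LL-only regions 1, ranked in the top 10% of all 3 lists of their line.

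The strongest FL-only regions gathered in 1 segment of chromosome Z. Of the 10 best-ranked, 7 lay there between 34761382 and 35030549, and 15 FL-only regions in all lay between 34750370 and 35030549. The segment starts 9586 bp beyond IFNKL1, an interferon kappa-like gene, and ends 15291 bp before RFKL, a riboflavin kinase-like gene. Its 9 coding genes all have LOC numbers, and it holds 6 annotated copies of the microRNA gene MIR7482. The median fold enrichment of these 15 regions was 12.3, 20.9 and 15.2 in FL replicates 1 to 3, and the region at 34790399 to 34790957, which lies outside genes, reached 25.5, 32.7 and 28.2. The FL libraries had 21, 27 and 22 peaks in the segment and the LL libraries 2, 1 and 4. One region of the segment was called in all 6 libraries. No library had a peak between 34790957 and 34947476.

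**Figure D2:**
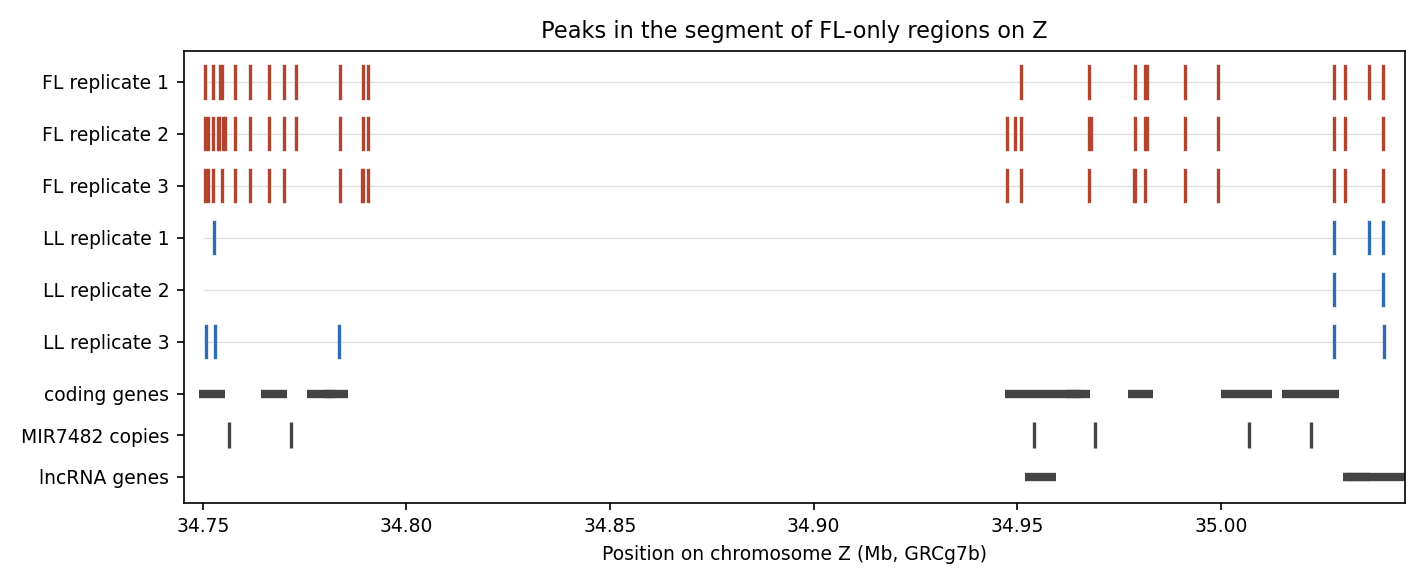
Peaks of each library (ticks, red for FL and blue for LL) and annotated genes (bars, and ticks for MIR7482 copies) along chromosome Z in Mb of GRCg7b. Inside the segment the FL libraries had 21, 27 and 22 peaks and the LL libraries 2, 1 and 4.

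The remaining FL-only regions of the 10 best-ranked lay elsewhere. The first of all was on chromosome 4 at 18695124 to 18695302, outside genes and 92570 bp from FMR1, which encodes an RNA-binding protein of translation control. Its fold enrichment was 40.9, 18.8 and 53.6 in FL replicates 1 to 3. The others lay on chromosome 2 at 119666265 to 119666488, inside a gene with a LOC number, and on chromosome 31 at 2426972 to 2427152, at the end of one, with no other named coding gene within 100 kb.

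The best-ranked LL-only region lay in the MHC-Y region of chromosome 16, at 1781922 to 1783210, at a gene end and 3175 bp from MHCY4, a non-classical major histocompatibility gene. Its fold enrichment was 22.1, 7.16 and 8.64 in LL replicates 1 to 3. A second region on chromosome 16 lay at 632780 to 633108 with no named coding gene within 100 kb. Others lay inside DENND5A, inside STAB2, a scavenger receptor of sinusoidal endothelium, inside DYSF (chromosome 4, 90226164 to 90226681), inside SPTY2D1, inside URB1 and inside PDE2A, a cyclic nucleotide phosphodiesterase. The last pair lay 18847 bp from MAPK8IP3 and 5443 bp from KCND2, a potassium channel gene. Exons and introns were not separated.

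A gene of the fixed lists was the nearest within 50 kb for 4 of the 85 LL-only and 1 of the 209 FL-only regions. In the list of fatty acid and triglyceride synthesis these were ME1 and INSIG2, a brake on sterol and fatty acid synthesis, for 2 of 85 LL-only regions against 0.149% of other regions called in exactly 3 libraries (Fisher's exact p = 0.00865, adjusted 0.26). An LL-only region at 55214093 to 55214742 on Z lay 260 bp from LPL and occupied its end at 55215002 in the LL libraries. The other end of LPL, at 55232438, was occupied in all FL libraries and in LL replicate 1, so no single end of LPL was occupied in all 6 libraries, a comparison made after the values were seen. LL-only regions also included one inside NR3C1, the glucocorticoid receptor gene, and FL-only regions one 4221 bp from IRS2, a substrate of the insulin receptor. No list passed after adjustment in either line.

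FL-only regions were more frequent than the library effects predicted, with 209 against 56.2 expected, a ratio of 3.72. LL-only regions numbered 85 against 62.8, a ratio of 1.35. Both together gave 2.47, and the highest of the other 9 splits of the libraries gave 1.08. The expected numbers are fitted to the same patterns, so a split that holds many of the regions is kept near 1. FL replicate 1 with LL replicates 1 and 2, for example, had 4356 regions against 4071 expected. The rank among the splits is therefore weak evidence of an effect of line. Among the 20 single patterns of 3 libraries the FL-only ratio was not the highest. FL replicates 2 and 3 with LL replicate 3 gave 28 regions against 0.867 expected, and FL replicate 2 with LL replicates 2 and 3 gave 33 against 1.46. In the other direction, FL replicates 1 and 3 with LL replicate 2 gave 12 against 127. Counts alone did not favour FL at every setting: with peaks of at least 178 bp there were 59 FL-only and 131 LL-only regions, and with equal list lengths 306 and 548. At equal list lengths the LL-only regions were 2.15 times their expected number. The FL-only ratio was 1.26 without FL replicate 3, 1.54 without FL replicate 2, 1.92 without LL replicate 1 and 1.91 without LL replicate 2, and the LL-only ratio was 0.877 without LL replicate 1 0.96 without LL replicate 2 and 2.28 without FL replicate 2. Together the ratio was 1.64 without FL replicate 2, 1.28 without FL replicate 3, 1.25 without LL replicate 2 and 1.55 without LL replicate 3.

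**Figure D3:**
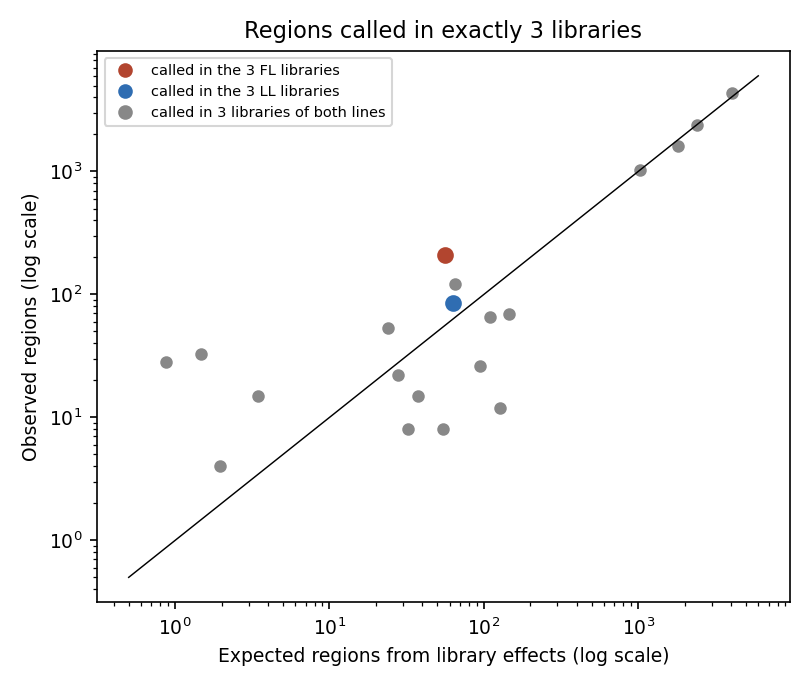
Observed against expected numbers of regions called in exactly 3 of the 6 libraries, 1 point per pattern, both axes on a log scale, with the line of equality. The FL-only pattern (red) had 209 regions against 56.2 expected and the LL-only pattern (blue) 85 against 62.8.

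Regions open in every bird were mostly at gene ends. Of the union regions, 7605 were occupied in all 6 libraries, and 66.7% of these lay at gene ends, against 8.77% of the 47378 regions found in a single library. Their median widths were 987 and 216 bp. FL replicate 2 had 12752 regions of its own, 41.8% of its regions, and LL replicate 1 had 22936, 31.3% of its regions, against 5.18% in LL replicate 2.

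Over the full lists the pairs of libraries did not rank by line. The pair with the strongest co-occupancy was FL replicate 1 and LL replicate 1, with a log2 odds ratio of 7.15 and 20382 regions called in this pair alone. The weakest was FL replicate 2 and LL replicate 1, at 1.43. Pairs within a line averaged 4.38 and pairs between lines 3.97. The difference of 0.41 was the 4th highest of the 10 splits (exact p = 0.4, smallest possible 0.1). At equal list lengths it was 0.85, the highest of the 10 splits, without LL replicate 2 it was -0.12, and without FL replicate 1 it was 1.79. With the Jaccard index, which depends more on list length, it was -0.0224 over the full lists. At equal list lengths the mean Jaccard index was higher within lines than between lines. Single pairs were at 0.395 to 0.574 within lines and at 0.351 to 0.638 between lines. The highest value, 0.638, was that of FL replicate 1 with LL replicate 1. The next highest between lines was 0.509, for FL replicate 1 with LL replicate 2.

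**Figure D4:**
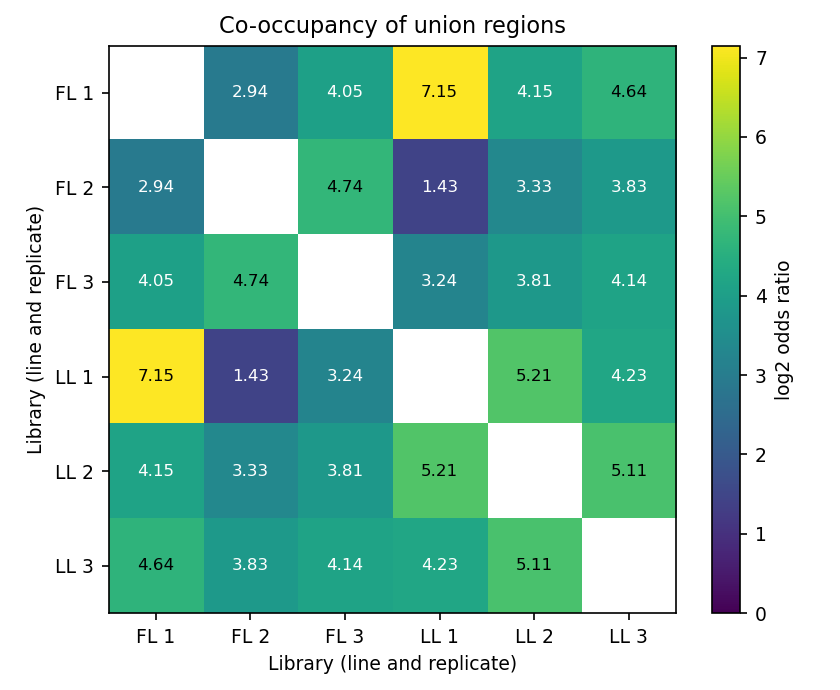
Log2 odds ratio of co-occupancy for each pair of libraries, over union regions occupied in at least 1 of the other 4 libraries, with the value in each cell and as colour. FL replicate 1 with LL replicate 1 stood highest at 7.15 and FL replicate 2 with LL replicate 1 lowest at 1.43.

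Peak numbers varied widely between libraries of a line. The lists held 37771 ± 18123 peaks in FL and 37451 ± 31378 in LL (SD, n = 3 each; exact permutation p = 1). Summits at gene ends made up 32.9% ± 9.33 in FL and 32.1% ± 11.2 in LL (exact permutation p = 0.9), and at equal list lengths FL exceeded LL by 7.67 points (exact permutation p = 0.1, the smallest possible). Chromosome Z held 6.89% ± 0.783 of the peaks in FL and 6.32% ± 0.204 in LL (exact permutation p = 0.3), and W held 24 to 61 peaks in each library. The local background at peaks on Z was 0.877 times that at autosomal peaks in FL and 0.919 times in LL (exact permutation p = 0.4). A local background cannot lie below the genome background, and 9.46% to 31.7% of the peaks of a list lay at it. This limits how low the ratio can fall, so it does not measure the copy number of Z. None of 14 such library values passed after Benjamini-Hochberg adjustment (lowest adjusted p 0.817).

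No relation of peak number to other values of a list passed its test in these few libraries. Over the 6 libraries, peak number and background had Pearson's r = 0.432 (exact permutation p = 0.41) and Spearman's rho = 0.0286 (p = 1), and r = 0.276 without the 2 libraries farthest from the median background. The background averaged 5.13 ± 3.02 in FL and 7.54 ± 1.54 in LL (SD, n = 3 each; exact permutation p = 0.3). With median fold enrichment, r was 0.182 and rho 0.257 (exact permutation p = 0.747 and 0.658), and r was 0.583 without the 2 farthest libraries. With median peak width, r was 0.616 and rho 0.6 (exact permutation p = 0.174 and 0.242), and r was 0.83 without the 2 farthest. In all 3 relations were computed, and the lowest adjusted p was 0.521, for median peak width.

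**Figure D5:**
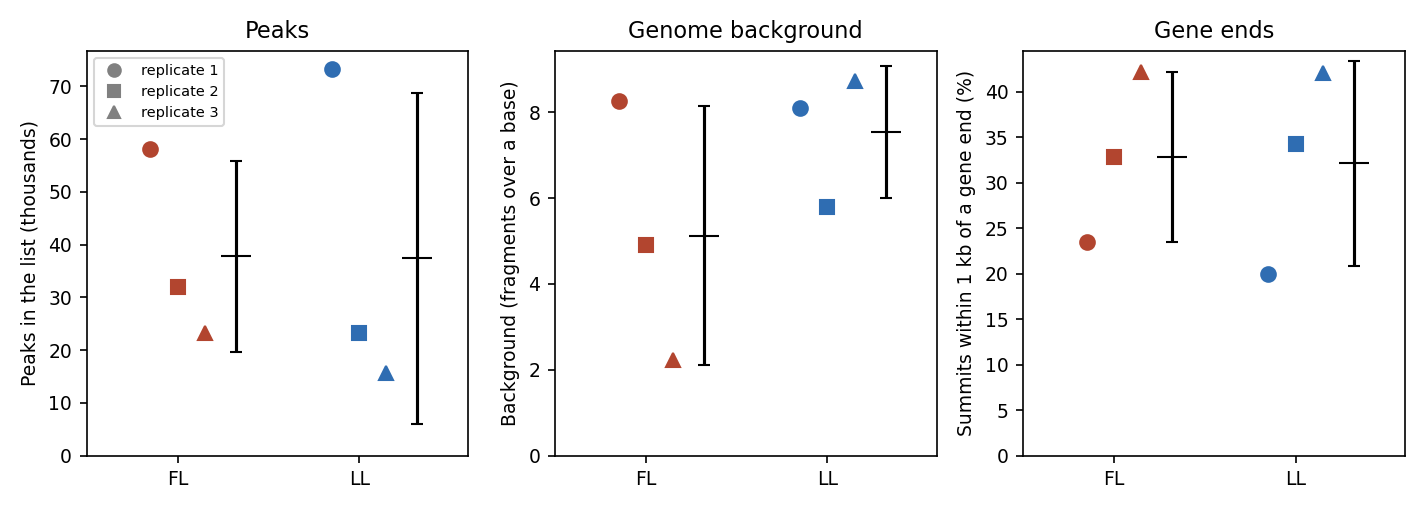
Peaks in each list (axis divided by 1000), genome-wide background in fragments over a base, and share of summits within 1 kb of a gene end in %, for the 3 FL (red) and 3 LL (blue) libraries, with mean and SD in black. LL replicate 3 had the highest background, 8.73, and the fewest peaks, 15628. Divided by the shortest peak of the list, the background was highest in FL replicate 1 (0.0565, against 0.0490 in LL replicate 3).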

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

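The alternatives without chromosomes Z, W, 16 and 31, with random lists matched on gene length, of the named and counted genes, and with only peaks of at least 178 bp were chosen after the results were seen. The outcomes without those chromosomes and with lists matched on gene length are not given here, so no support is drawn from them. The cause of the changes below was not tested, except that fewer libraries loosen the criterion for one-line regions. With −log10 q of at least 5, FL minus LL in peaks per library was -3849, 164 regions were called in one line (126 FL-only, 38 LL-only), 0 gene-end tests of lists were higher and 1 distal test was lower. With equal list lengths, 854 regions were called in one line, 548 of them LL-only at 2.15 times the expected number, 1 gene-end test was higher, 6 distal tests were higher and 1 was lower. With gene ends within 3 kb, the difference in gene-end share was -0.0186 points and 1 gene-end test was higher. With peaks of at least 178 bp, FL minus LL in peaks was -8569, and 190 regions were called in one line (59 FL-only, 131 LL-only). Over the full lists the within minus between difference was -0.0224 with the Jaccard index and -0.0090 with 50% reciprocal overlap. In at least 2 of 3 libraries, 2966 regions were called in one line (1656 FL-only, 1310 LL-only).

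Leaving out each library in turn, FL minus LL ranged from -10592 to 18299 in peaks, from -5.33 to 5.74 points in gene-end share and from -10.5 to 10.5 points in occupied adipocyte identity genes. Co-occupancy ranged from -0.12 to 1.79. Regions called in one line ranged from 504 to 2840, FL-only from 235 to 2026 and LL-only from 95 to 2041. Observed over expected ranged from 1.25 to 2.16 for both lines, from 1.26 to 4.63 for FL-only and from 0.877 to 2.28 for LL-only. Higher gene-end tests ranged from 0, without the library that held both, to 2, and higher distal tests from 7 to 13. Whether the replicate numbers pair the libraries is not settled. Across regions, deviations of occupancy from the line mean correlated at 0.312, 0.152 and -0.000359 in same-numbered libraries. FL replicate 2 and LL replicate 3 correlated at 0.291, and the remaining pairs lay between -0.334 and 0.00135. The deviations cancel within a line, so these correlations are not independent of each other. With the number as a replicate block, FL minus LL was 320 in peaks (exact p = 1), -2.41 in background (exact p = 0.5), 0.747 points in gene-end share, 1.75 points in occupied adipocyte identity genes and -0.177 in their distal ratio, where 0.25 is the smallest possible p. Of 210 comparisons of list values with an alternative that could move them by over 1 SD, 167 moved by at most 1 SD and 43 by more, 21 of 60 with equal list lengths, 11 of 30 with distal windows of 20 kb, 6 of 30 with gene ends within 3 kb and 5 of 60 with −log10 q of at least 5. The SD here is that of the 3 libraries of a line in the main setting, so a wide spread hides large moves. Fibroblast genes in LL averaged 48.3% (SD 41.6) and fell to 15% in each LL library at equal list lengths. That move counted as within 1 SD. The 167 therefore do not show that the list values are stable. With windows of 20 kb, 12 distal tests were higher, and the endothelial ratio was 1.91 in FL and 2.32 in LL. The alternative with assembled chromosomes only was not run, since it removes no peak, and those of motifs and GC content were not run. Depth is known only through the background, so low-signal regions missing from a list may have been missed: with −log10 q of at least 5, 126 FL-only regions were called.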

Other observations

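The tests of copy number, repeated copies and placement on chromosome Z, of depth, of other cell types, and of the numbers of FL-only and LL-only regions were chosen after the result was seen, as were the values near chromosome ends given in the next paragraph.

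Several FL-only regions lay at the very ends of chromosomes. Of the 209 FL-only regions 18 (8.61%) lay within 100 kb of a chromosome end, against 0.733% of the other regions called in exactly 3 libraries (Fisher's exact p = 2.59e-13, with neighbouring regions not independent) and 3 of the 85 LL-only regions (3.53%). The ends of a chromosome were taken as its first base and its last annotated gene or peak. Examples chosen after their values were seen are chromosome 9 at 812 to 975, chromosome 3 at 2912 to 3113, chromosome 7 at 8602 to 8788, chromosome 34 at 5554 to 5770, 11350 bp from WNT1, and chromosome 1 at 11133 to 11427, at an end of FLNC, the filamin C gene. Chromosome 16, which carries the major histocompatibility genes, had 6 FL-only and 6 LL-only regions. Skeletal muscle genes were at 40% in FL replicate 2, and at 10% there with −log10 q of at least 5.

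The first pattern is the cluster of 15 FL-only regions in 280 kb of chromosome Z. In 10000 random reassignments of the FL-only label among regions called in exactly 3 libraries, no 300 kb window held more than 6, so random placement is argued against (permutation p = 0.0001, the smallest the reassignments can give). A copy number gain of the whole segment in FL stays open: the cluster's local background was 1.0 times the genome background in the median FL library and 1.25 times in FL replicate 2, but the genome background is the lowest value a local background can take, so a gain from a lower level would not be seen. Reads shared between repeated copies also stay open, since the segment holds 6 copies of MIR7482 and the treatment of such reads is not given in the sources used here. A sequence difference or a loss of copies in LL, and a difference in chromatin between the lines, were not tested.

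The second pattern is the resemblance of FL replicate 1 and LL replicate 1. At equal list lengths the pair's log2 odds ratio was 4.91, still the highest of 15 but close to the 4.64 of FL replicates 2 and 3, so list length alone is not decided. Depth is open too: LL replicate 3 had as high a background but 0.238 times the mean peak number of the pair, and this rests on 1 library. More nuclei of other cell types may add to the resemblance, yet at equal list lengths 2 of 5 lists were higher in the pair. Endothelial genes were at 36.7% against 13.3% and lymphocyte genes at 32.1% against 23.2%, while fibroblast genes were at 17.5% against 21.2%, myeloid genes at 25% against 32.1% and smooth muscle genes at 5.56% against 11.1%, each of the lower lists within 1 SD of the other 4 libraries.

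The third pattern is the excess of FL-only regions. With only peaks of at least 178 bp the observed over expected ratio was 5.16, so it did not fall. That filter changes the list lengths too, so this does not decide whether peak length is the cause of the ratio. Without regions within 100 kb of chromosome ends the ratio was 3.82. Only 18 of the 209 FL-only regions lay there, too few to make up the excess, so the counts had fixed this outcome in advance. The model of library effects behind the ratio was also missed by patterns that mix the lines, at 0.0948 to 32.3 times expected. The ratio was 1.26 without FL replicate 3, 1.54 without FL replicate 2, 1.91 without LL replicate 2 and 1.92 without LL replicate 1. The larger number of FL-only than LL-only regions is another matter: with peaks of at least 178 bp FL-only regions were 0.45 times the LL-only regions, so the shorter peaks of the FL lists may account for it. List length stays open beside peak length, since the filter changes both and equal list lengths with short peaks kept gave 306 FL-only and 548 LL-only regions, and so do a batch or caller setting that followed line and a difference between the lines, both untested.

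The 6 libraries can be divided into groups of 3 and 3 in 10 ways, too few for a share under 0.05. For regions called in one group, 5 of the 10 splits gave as many as the 294 of FL and LL, with a highest other value of 4384. That split set FL replicate 1 and LL replicates 1 and 2 against the rest, and 4356 of its regions were in the first group, where library effects alone predicted 4071. For the observed over expected ratio of both lines together, 1 of 10 splits, the real one, reached 2.47, and the highest other was 1.08. Splits that hold many of the fitted regions are kept near 1, so this rank decides little. For co-occupancy 4 of 10 splits reached 0.41, with a highest other of 1.23. For coding genes with an end called in one group, 5 of 10 splits gave at least 57, with a highest other of 461, for FL replicates 1 and 3 with LL replicate 1.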
